A study of Homo sapiens with 4 samples.

How the data were processed

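Total RNA of HepG2 and K562 cells carrying a plasmid with an siRNA against ADAR or a scrambled control was extracted with TRIzol and labelled with biotin for Affymetrix whole-transcript exon arrays, per the labels' protocols. There were 4 arrays, 1 per line and arm, so no group was replicated. The deposited table holds an intensity per transcript cluster on a linear scale, with all values positive. RMA and the build hg18 are named in the submitters' processing notes, with no version; any later step is not given in the sources used here. The column medians of the deposited intensities were 36.7, 36.1, 36.7 and 37.0, and the SDs of their log2 values 1.88, 1.95, 1.84 and 1.75. Signal over background per probe was not analysed here.

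The table had 17881 transcript clusters. In the platform annotation 14432 had 1 gene symbol, 2408 several and 1041 none, and the last 2 kinds were named in no result. By Entrez number, 14404 single symbols were found in a RefSeq gene table of a later assembly, which was used for names alone, and 0 symbols changed. A gene with several clusters (197 genes) took the one with the highest mean, giving 14232 genes. The design had assumed values on a log2 scale; since the deposited intensity is linear, log2 was taken without an offset and the tests were kept. A gene was kept in a line if the mean of that line's 2 log2 values was at or above the median of all genes' means. Coordinates are not given, because the builds differ.

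Within a line the result was the log2 difference, ADARkd minus SCR, and the number of kept genes at least 2-fold apart, with no p-value. The shared effect was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, Benjamini-Hochberg, threshold 0.05) with line and arm as terms, on genes kept in both lines, leaving 1 residual degree of freedom. The same model gave K562 minus HepG2 on genes kept in either line, with a 2-fold bound added. Gene lists (29, fixed before the data were examined) were tested with limma's camera at a preset correlation of 0.01 and an estimated one, and with fry, if at least 5 members were kept. Within a line, a list's median was placed among 10000 random lists of its size matched on mean expression (2000 in the alternatives). The difference between the lines' knockdown effects leaves no residual degrees of freedom and was not tested. Figures were drawn with matplotlib 3.10.9.

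The genes named were the 12 highest and 12 lowest differences per line among kept genes, and the 10 largest each way in the line comparison. For the shared effect, where no gene passed, they were the 10 each way whose smaller difference of the 2 lines was largest. The ADAR family and up to 4 members of each list with the largest difference were added. XIST and genes of the Y chromosome were left out. Genes outside this rule are said to have been chosen after their values were seen.

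The fits were tested on simulated data: 20 runs per setting over 6204 genes, with the spread of the real arrays and 200 genes altered. For the shared effect, a log2 change of 1 was recovered in 66.9% of altered genes on average (0 to 91%) and a change of 2 in 99.9%. False calls there exceeded the nominal rate: they made up 12.6% of calls on average at a change of 1, 10.0% at a change of 2 and 8.82% at a change of 3, and over 5% in 16, 15 and 16 of the 20 runs. With no gene altered, 9 of 20 runs still made calls, up to 37. The prior degrees of freedom were 7.60 as simulated, and estimates from 1 residual degree of freedom ran from 5.83 to infinite. At a change of 1, false calls averaged 14.4% in the 17 runs with an estimate above the simulated value and 2.57% in the other 3. With the simulated prior put in place of the estimates, they averaged 4.69%, 4.46% and 4.72% at changes of 1, 2 and 3. They were then still over 5% in 10, 9 and 8 of the 20 runs, so a run over 5% is not by itself a fault. For K562 minus HepG2 with its 2-fold bound, false calls averaged 6.65%, 4.25% and 4.00% at changes of 1, 2 and 3, with 42.2%, 99.6% and 100% recovered. False calls of this comparison were over 5% in 15, 5 and 4 of the 20 runs, against 6, 3 and 1 with the simulated prior. With no gene altered, 10 of 20 runs made calls, up to 14. The simulated line comparison altered 200 of 6204 genes kept in both lines, while the real one called 2014 of 8028 genes kept in either. Its simulated rates of false calls therefore need not carry over to the real comparison. Adjusted p-values of both comparisons are therefore approximate. By the mean share of false calls, those of the shared effect ran too small in simulated data, and so did those of K562 minus HepG2 at a change of 1. Of 200 simulated lists with no shift, 3.5% lay outside the central 95% of random lists, and a list shifted by 0.5 lay at percentile 100. The simulated genes were independent and the lists were not matched on expression. They therefore do not show how often a list of co-expressed genes would lie outside.

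Alternatives were quantile normalization, centring on the column median, loess against mean expression within a line, log2(value + 16), the mean of all clusters of a gene, no filter, a filter at the 75th percentile, a 1.5-fold threshold, eBayes without the trend or robust, no block, and leaving out arrays. Added after the data were seen were the leave-one-out fits of the line comparison without the arm term, the shared effect without either line's arrays, the stricter filter for lists, and the offset for ADAR.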

Results

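Gene expression was measured on exon arrays in a pair of human cell lines with and without knockdown of ADAR, the enzyme that deaminates adenosine to inosine in double-stranded RNA. HepG2 is a hepatocellular carcinoma line and K562 is a chronic myeloid leukaemia line with erythroid features. Cells of each line had been stably transfected with a plasmid carrying an siRNA against ADAR (ADARkd) or a scrambled sequence (SCR). The stated purpose was to learn how ADAR acts on alternative splicing across the genome, and the values used here are its gene-level part. There were 4 arrays, 1 for each line and arm. Median intensities were 36.7 and 36.1 on the SCR and ADARkd arrays labelled HepG2, and 36.7 and 37.0 on those of K562. The values covered 14232 genes, of which 7116 were kept in each line, 6204 in both and 8028 in either. Across genes, which are not replicates, the log2 values of SCR and ADARkd arrays correlated at r = 0.977 for HepG2 and 0.993 for K562. The SCR arrays of the 2 lines correlated at 0.848. The number of arrays limits the precision of every value: with 1 array per arm, no difference within a line has a replicate check.

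The first question was whether the targeted transcript was lower in the knockdown arrays. ADAR stood at 8.96 on the log2 scale in the SCR array labelled HepG2 and at 7.27 in its ADARkd array, a difference of -1.69. That is 3.23-fold lower and leaves 31.0% of the SCR intensity. In K562 the levels were 7.99 and 6.78, a difference of -1.21, which is 2.32-fold lower and leaves 43.2%. ADAR ranked as number 25 from the lowest difference among the 7116 genes kept in HepG2 and as number 7 in K562. Its paralog ADARB1, the second catalytically active deaminase, differed by 0.11 and -0.16. ADARB2, a family member without known editing activity, differed by -0.74 in the arrays labelled HepG2, and by 0.27 in K562, where it lay under the expression filter. ADAD1 was under the filter in both lines.

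The levels of cell type markers were compared next, since they bear on what each array holds. On the arrays labelled HepG2, genes of the hepatocyte were low: of 28 measured markers, 2 lay at or above the median of all genes, and in K562 4 did. The 2 were CPS1, the mitochondrial enzyme that starts the urea cycle, at 10.9 in SCR and 10.6 in ADARkd, and FOXA1, a pioneer factor of endoderm, at 6.13 and 6.23. ALB (albumin) stood at 3.04 and 2.97 there, AFP (alpha-fetoprotein) at 2.89 and 2.85, APOA1 at 4.85 and 4.89, and TTR at 3.71 and 3.71. These 4 genes were chosen after their values were seen. Of 17 measured erythroid markers, 14 were kept in K562 and 2 in HepG2. Because of the hepatocyte markers, the arrays are called labelled HepG2 here, and every direction drawn from them carries that limit. Of 14 fibroblast and stromal markers, 8 were kept on these arrays and 2 in K562, and of 14 lymphocyte markers none was kept in either line.

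**Figure D1:**
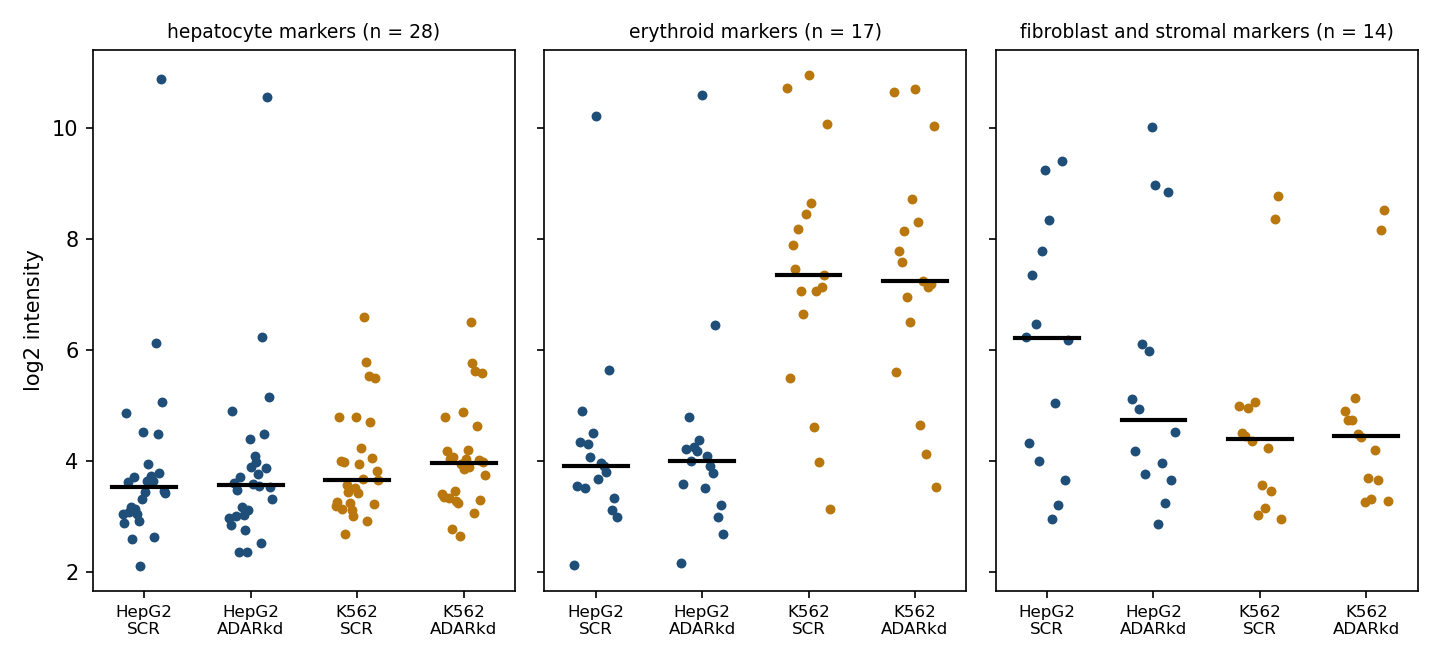
Log2 intensity of each measured hepatocyte (n = 28), erythroid (n = 17) and fibroblast or stromal (n = 14) marker on each of the 4 arrays. Each point is a gene and each bar is the median of the panel's genes on that array; most erythroid markers sit higher on the K562 arrays, and most hepatocyte markers are low on all 4.

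K562 was compared with the arrays labelled HepG2 to describe the 2 backgrounds in which ADAR was lowered. HBZ, an embryonic globin, was higher by 8.55 ± 0.20 on the log2 scale (SE, 2 arrays per line; limma adjusted p = 4.1e-06), and RHAG, of the erythrocyte Rh complex, by 6.79 ± 0.20. GTSF1 (8.11), LCP1, an actin bundler of blood cells (7.31), LAPTM5 (6.37), CD53 (5.99), TEX15 (5.79), the kinase BTK (5.59), the ferroxidase HEPH (5.54) and PRKCB (5.28) followed. On the arrays labelled HepG2, CPS1 led with a K562 minus HepG2 difference of -7.47 ± 0.21 (limma adjusted p = 4.94e-06). It was followed by TM4SF1 (-6.93), the actin bundler PLS3 (-6.49), the matrix proteoglycan LUM (-6.49), APP (-6.39), the protease inhibitor SLPI (-6.37), PDE3A (-6.34), the matrix protein EFEMP1 (-6.30), the oncostatin M receptor OSMR (-6.29) and MYO1E (-6.12). All 20 genes lay under the filter level on their dimmer side, at means of 2.14 to 3.80 on the arrays labelled HepG2 and 3.14 to 4.17 in K562. Background can set such dim values and was not analysed here, so the sizes and order of these differences are uncertain.

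By limma with Benjamini-Hochberg adjustment, 2014 of 8028 genes passed at an adjusted p under 0.05 and a difference of at least 2-fold. Of these, 830 were higher in K562 and 1184 higher on the arrays labelled HepG2. Of the erythroid markers, 13 passed as higher in K562 and 0 as higher on the other side. Among the hepatocyte markers 2 passed as higher in K562 and 1, CPS1, as higher on the arrays labelled HepG2. Fibroblast and stromal markers split 1 against 5, and megakaryocyte and myeloid markers 5 against 1. Acute phase and complement genes split 0 against 4. With the filter at the 75th percentile 1159 genes passed. The 2 arrays of a line differ in arm, and nothing says that they came from separate cultures. The 1 residual degree of freedom is the difference between the 2 lines' knockdown differences. These p-values and errors rest on that value and on the spread assumed across genes, not on replicate arrays.

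The knockdown comparison on the arrays labelled HepG2 asked which transcripts differed where ADAR was 3.23-fold lower. The neutrophil chemokine CXCL8 had the highest difference: its measured intensity in ADARkd was 24.9-fold higher than its SCR level of 4.36 (log2 difference 4.64), and the cytokine IL6 stood at 7.61 against 3.16 (4.46, or 2.94 as the mean of all its transcript clusters). Both SCR levels lay under the filter level of 5.31, where background can set the value, so the sizes and the order of these differences are uncertain. IL1A, another cytokine, differed by 2.32, the carboxypeptidase CPA4 by 3.06, and EPGN, a ligand of the EGF receptor, by 2.75. CLDN1 of tight junctions (2.44), the matricellular protein CCN1 (2.35), MYEOV (2.24), the tetraspanin TSPAN8 (2.22), MB21D2 (2.14), CCNQ (2.07) and the protease inhibitor SPINK6 (2.04) completed the 12 highest.

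At the other end COL3A1, a fibrillar collagen, differed by -2.42, COL15A1 of basement membranes by -2.34, the hyaluronan-degrading CEMIP by -2.37, and LOX, which crosslinks collagen and elastin, by -2.18. CPED1 was the lowest at -2.81. HPD, an enzyme of tyrosine breakdown, stood at -2.48, PTGS1, a cyclooxygenase, at -2.34, GPNMB at -2.30, CDON at -2.04, the sodium channel subunit SCNN1A at -2.04, C1orf21 at -2.03 and TMT1A at -2.02. In K562, CPED1 differed by 0.10, COL3A1 by 0.27 and LOX by 0.27, the last 2 under the filter there. The dimmer array lay under the filter level for 5 of the 12 highest genes and 7 of the 12 lowest. In all, 287 of 7116 genes (4.03%) were at least 2-fold apart, 175 higher and 112 lower in ADARkd. The higher share was 61.0%, against 47.0% after quantile normalization (124 higher, 140 lower) and 46.4% after loess (127 higher, 147 lower). Both settings bring the median difference of kept genes from 0.11 to 0.01.

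Of the gene lists fixed before the data were examined, the targets of NF-kB and cytokine signalling lay farthest up on the arrays labelled HepG2. Their median difference was 0.78 over 15 kept members, at percentile 100 among 10000 random lists matched on expression. Of the 15, 11 were at least 1.5-fold higher, among them CXCL2 (1.74) and TNFAIP3, a feedback inhibitor of NF-kB (1.62). The 1 lower member was the chemokine CCL5 at -1.16, named after its value was seen. Genes of ATF4 and the unfolded protein response had a median of 0.35 over 31 members (percentile 99.6). STC2 (1.45), the chaperone cofactor SDF2L1 (1.21), the glutathione-degrading CHAC1 (1.19) and PPP1R15A (0.89) led them, and 7 members were 1.5-fold higher and 0 lower.

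Core spliceosome genes had a median of 0.31 over 40 members (percentile 99.2), with 6 at least 1.5-fold higher and 0 lower. SNRPF (1.07) and SNRPD1 (0.95), both Sm proteins of the small nuclear ribonucleoproteins, PRPF38A (0.96), and PRPF31 of the tri-snRNP (0.72) led these. Cell cycle genes had a median of 0.31 over 33 members (percentile 98.6), led by the G1 cyclins CCND1 (1.20) and CCNE1 (1.17) and the phosphatase CDC25A (0.81). Apoptosis regulators had a median of 0.40 over 14 members (percentile 99.0), with the anti-apoptotic BCL2L1 at 1.14 and the pro-apoptotic PMAIP1 at 0.82. After quantile normalization and loess the medians were 0.22 and 0.20 for ATF4 and the unfolded protein response, 0.19 and 0.18 for the spliceosome and 0.18 and 0.17 for the cell cycle. With the filter at the 75th percentile these 3 lists lay inside the central 95% of random lists (percentiles 95.4, 95.65 and 94.8), and the apoptosis median was 0.63 (percentile 98.8).

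Fibroblast and stromal markers had the lowest median on the arrays labelled HepG2, -0.83 over 8 members (percentile 0). Fibronectin, FN1, differed by -1.80, the surface protease FAP by -1.66 and the collagen chain COL1A1 by -1.12, beside COL3A1. LUM, at 0.78, and DCN, at 0.64, were higher; DCN was named after its value was seen. With no filter on low values the median was -0.30 (percentile 0). Hypoxia and glycolysis genes had a median of -0.25 over 21 members (percentile 0.01), with 5 members 1.5-fold lower and 0 higher. NDRG1 (-1.04), the enolase ENO2 (-1.0), the oxygen sensor EGLN3 (-0.91) and the histone demethylase KDM3A (-0.84) were the lowest. Replication-dependent histones had a median of -0.11 over 17 members (percentile 1.52), with H2AC8 at -0.87 and H2BC5 at 0.66, and lay inside the central 95% after quantile normalization (percentile 11.9) and loess (4.85).

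The double-stranded RNA sensors and effectors, which include proteins that detect unedited RNA, had a median of 0.28 on the arrays labelled HepG2 over 12 members (percentile 89.8). After quantile normalization and loess the median was 0.17 and 0.18. OAS3 differed by 0.70, the kinase TBK1 by 0.65 and TRIM25 by 0.61. Interferon-stimulated genes had a median of -0.07 over 19 members (percentile 7.53), which was -0.19 after quantile normalization, -0.18 after loess and -0.02 with no filter. SAMD9 differed by 1.39, and PARP9 (-0.91), XAF1 (-0.82) and IFITM1 (-0.73) the other way. Known targets of ADAR editing had a median of 0.18 over 17 members, close to the 0.12 of random lists (percentile 69.7), of 0.04 after either quantile normalization or loess, and of 0.07 with no filter. Among them were IGFBP7 at -1.25 and the proteasome subunit PSMB2 at 0.78. RNA-binding proteins that associate with ADAR had a median of -0.08 over 10 members (percentile 7.96), or -0.21 after quantile normalization and -0.20 after loess, with ZC3H12A at 0.94 and STRBP at 0.76.

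Splicing factors outside the core spliceosome lay nearer to the random lists on these arrays. SR proteins had a median of 0.17 (percentile 61.2), with TRA2B at 0.97 and SRSF3 at 0.62. The hnRNP proteins had a median of 0.12 (percentile 39.0), with HNRNPH2 at 0.79, and other splicing regulators 0.08 (percentile 28.1), with RBM10 at 0.54. Nonsense-mediated decay genes had a median of 0.25 (percentile 86.8), with the exon junction protein MAGOH at 1.16, and microRNA biogenesis genes 0.06 (percentile 34.7), with TUT4 at -0.55. After quantile normalization and loess the medians were 0.09 and 0.04 for SR proteins, 0.01 and -0.01 for hnRNP proteins, -0.03 and -0.03 for other regulators and -0.06 and -0.05 for microRNA genes, so the last 2 lists turned negative under both and the hnRNP list under loess. The other regulators were also negative with no filter (-0.0045).

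The remaining lists on the arrays labelled HepG2 lay inside the central 95% of random lists. Mitochondrial respiratory chain genes had a median of 0.31 (percentile 96.9), with SDHC at 1.03 and NDUFA9 at 0.82, and lay outside after quantile normalization (0.24, percentile 99.2), with log2(value + 16) (97.95) and as the mean of all clusters (97.8); after loess the median was 0.18 (96.65). Targets of p53 had 0.16 (percentile 71.6), with TRIAP1 at 1.62, GADD45A at 1.13 and ZMAT3 at -1.35, and 0.04 with no filter. Cytosolic ribosomal proteins had -0.04 (percentile 7.01), with RPL28 at -1.45, -0.14 after loess, -0.15 with the filter at the 75th percentile (percentile 1.25) and 0.19 with no filter (percentile 85.3). Heme synthesis and iron genes had 0.10 (percentile 48.2), with the mitochondrial iron importer SLC25A37 at -1.25 and ferritin light chain, FTL, at -0.92. Liver lipid and sterol genes had 0.10 (percentile 40.9), with the fatty acid elongase ELOVL6 at 1.40 and HMGCS1 at 0.68. Immediate early and heat shock genes had 0.05 (percentile 27.4), with HSPE1 at 0.97. Acute phase and complement genes had 0.03 over 5 members (percentile 38.7), with the complement proteases C1R at -1.67 and C1S at -1.66. After quantile normalization and loess the lipid and sterol median was -0.03 and -0.04 and the immediate early median -0.08 and -0.09. That of the acute phase list was -0.0044 after loess and -0.12 with no filter, and with the filter at the 75th percentile that of the lipid and sterol list was -0.05. The heme and iron median was 0.07 after loess and 0.05 with the stricter filter.

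**Figure D2:**
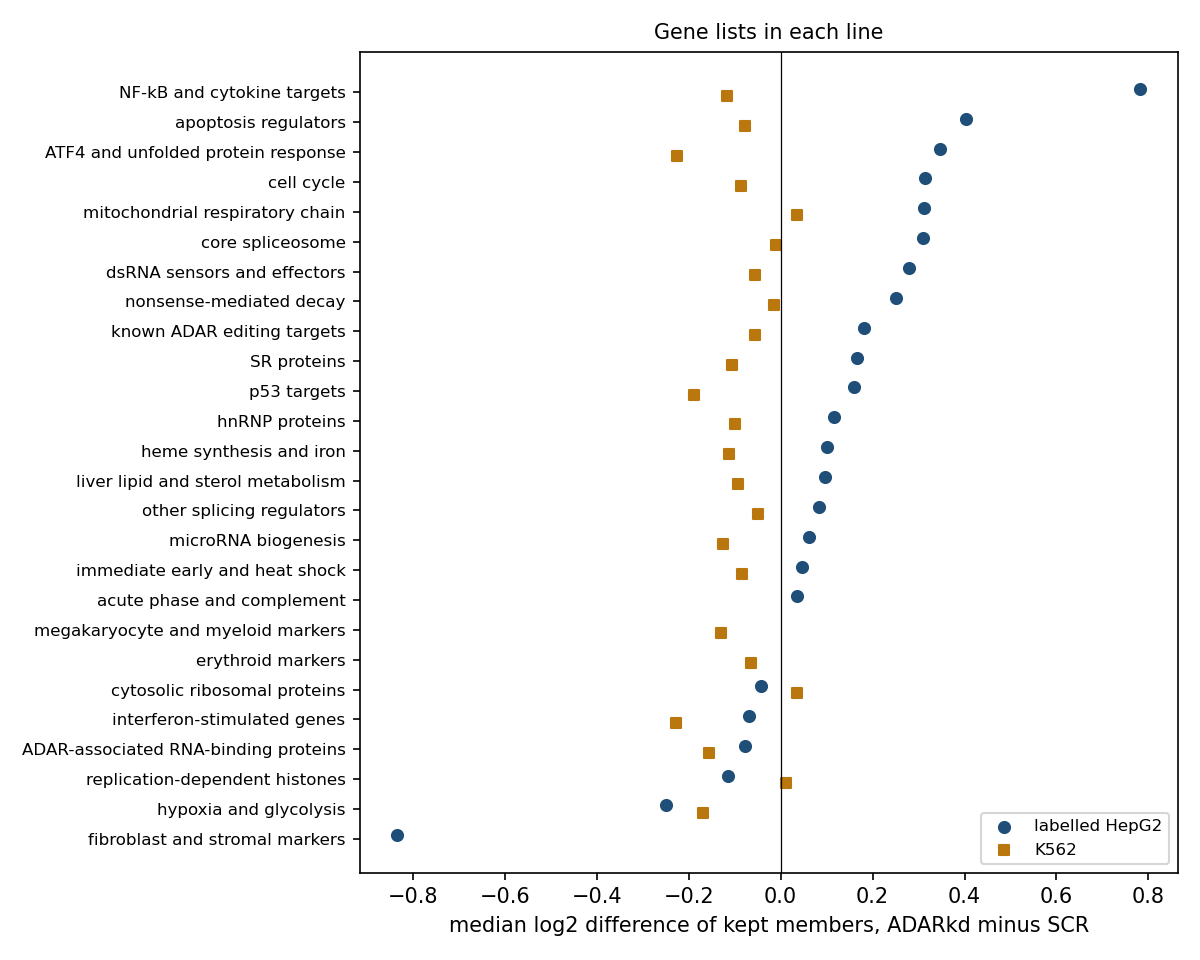
Median log2 difference, ADARkd minus SCR, of the kept members of each gene list with at least 5 of them, on the arrays labelled HepG2 (circles) and in K562 (squares). NF-kB and cytokine targets sit at 0.78 and fibroblast and stromal markers at -0.83 on the arrays labelled HepG2, while the K562 medians run close to 0.

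In K562 the same comparison gave far smaller differences. ARLN was the lowest in ADARkd at -1.78 (-1.13 as the mean of all its transcript clusters), then PMS2CL, a pseudogene of the mismatch repair gene PMS2, at -1.54, the neuropeptide NTS at -1.51 and XAGE3 at -1.49. The dynein adaptor BICD1 (-1.32), the alpha-tubulin TUBA1B (-1.31), ADAR (-1.21), MORC4 (-1.08) and TCAF1 (-1.07) also lay under -1. DNAJC8 (-0.90), RPS10P7 (-0.89) and the lysosomal acetyltransferase HGSNAT (-0.83) came next. At the high end were the ribosomal protein RPL35 (1.13) and ABAT, which degrades the neurotransmitter GABA (1.04). Below them came OR2L3 (0.94), CPN1 (0.92), THYN1 (0.91), LYPD2 (0.90), ENTPD1-AS1 (0.90), the platelet glycoprotein GP9 (0.84), MYCN (0.82), the heat shock factor HSF1 (0.81), ZSCAN20 (0.74) and RTP5 (0.66). PMS2CL, TUBA1B, RPS10P7, XAGE3 and RPL35 have close paralogs or pseudogenes whose transcripts can bind the same probes, so their values are uncertain. The dimmer array lay under the filter level of 5.28 for 5 of the 12 lowest genes and 3 of the 12 highest, so their sizes and order are uncertain as well.

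Of 7116 genes kept in K562, 11 (0.155%) were at least 2-fold apart, 2 higher and 9 lower in ADARkd. The SD of the differences across genes was 0.19, against 0.47 on the arrays labelled HepG2. The count was 30 with no filter on low values and 1 with the filter at the 75th percentile.

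ATF4 and unfolded protein response genes had a median of -0.23 over 30 members in K562 (percentile 0), with the cystine transporter SLC7A11 at -0.69, DDIT3 at -0.69, and the serine synthesis enzymes PSAT1 at -0.65 and PHGDH at -0.59. Interferon-stimulated genes had a median of -0.23 over 8 members (percentile 1.55), with IFI6 at -0.55 and TRIM21 at -0.47. Hypoxia and glycolysis genes had -0.17 over 20 members (percentile 0.83), with NDRG1 at -0.57, PDK1 at -0.55 and P4HA1 at -0.55. This list lay inside the central 95% after quantile normalization (-0.06, percentile 5.55) and with no filter (-0.13, 3.75), and the interferon list did so with no filter (0.10, 65.85). The ATF4 median was -0.14 after quantile normalization (percentile 0.05). Core spliceosome genes had -0.01 over 40 members (percentile 98.6), respiratory chain genes 0.04 (percentile 99.1) and cytosolic ribosomal proteins 0.04 (percentile 98.4). Random lists at those levels had medians near -0.07, and after quantile normalization the 3 medians were 0.07, 0.12 and 0.14. The ribosomal proteins lay inside the central 95% after loess (percentile 97.375) and with the filter at the 75th percentile (92.35).

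Lists inside the central 95% in K562 included NF-kB and cytokine targets (-0.12, percentile 23.6), double-stranded RNA sensors (-0.05, 63.3), editing targets (-0.06, 68.1) and proteins that associate with ADAR (-0.16, 8.79). The splicing lists were SR proteins (-0.11, 22.7), hnRNP proteins (-0.10, 16.2) and other splicing regulators (-0.05, 72.5). Nonsense-mediated decay stood at -0.02 (85.9) and microRNA biogenesis at -0.13 (18.7). Erythroid markers had a median of -0.06 over 14 members (58.3), with ALAS2, the first enzyme of erythroid heme synthesis, at -0.33, and heme and iron genes -0.11 (27.2). Megakaryocyte and myeloid markers had -0.13 (20.9), with GP9 at 0.84 and LYZ at -0.66. Cell cycle (-0.09, 30.6), p53 targets (-0.19, 2.55), apoptosis (-0.08, 51.0), lipid and sterol (-0.09, 30.0), immediate early (-0.08, 43.2) and histone genes (0.01, 96.7) completed the lists. The histones lay outside after quantile normalization (0.10, 97.6) and with no filter (0.08, 99.5). After quantile normalization and loess the K562 medians moved toward 0: NF-kB targets to -0.06 and -0.05, proteins that associate with ADAR to -0.08 and -0.09, SR proteins to -0.05 and -0.04, hnRNP proteins to -0.03 and -0.03, microRNA genes to -0.05 and -0.05, and heme and iron genes to -0.03 and -0.03. Myeloid markers went to -0.04 and -0.05, cell cycle genes to -0.01 and -0.01, p53 targets to -0.11 and -0.12, lipid and sterol genes to -0.02 and -0.02 and immediate early genes to -0.02 and -0.03. After loess the K562 medians of the sensors, editing targets, other splicing regulators, decay genes, erythroid markers and the spliceosome turned positive, and that of the apoptosis list did so after quantile normalization.

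The effect shared by the lines was asked with both pairs of arrays in 1 model. ADAR had the largest shared difference relative to its error, -1.45 ± 0.22 (SE, lower in 2 of 2 lines), with an unadjusted p of 0.00014 and a limma adjusted p of 0.871. HGSNAT followed at -1.66 on the arrays labelled HepG2 and -0.83 in K562. Also lower in both lines were BTBD2 (-0.80 and -0.60), NDRG1 (-1.04 and -0.57), the integrin subunit ITGB5 (-0.61 and -0.56), the interferon-induced IFI6 (-0.71 and -0.55), KDM3A (-0.84 and -0.54), PAXBP1 (-0.71 and -0.53), the thioredoxin-binding TXNIP (-0.59 and -0.52) and PDE9A (-0.52 and -0.56). Higher in both were CPN1 (0.79 and 0.92), the mitochondrial fission GTPase DNM1L (0.80 and 0.60), DMAC1 (0.60 and 0.59), the proteasome activator subunit PSME2 (0.60 and 0.57) and SNRPF (1.07 and 0.56). GEMIN2, which helps assemble small nuclear ribonucleoproteins, stood at 0.56 and 0.59, TBCA at 0.55 and 0.57, PDSS1 at 0.67 and 0.53, CFL2 at 0.51 and 0.51 and H2BC5 at 0.66 and 0.44.

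None of these passed: limma called 0 of 6204 genes for the shared effect, with 179 at an unadjusted p under 0.05. Adjusted over the list alone, ADAR passed in the ADAR family and no member of another list did. With each array's values centred on their median, limma called 7 genes, ADAR among them with an adjusted p of 0.000658; its adjusted p over all settings is given with the other alternatives. With 1 residual degree of freedom the estimate of the error depends heavily on the spread assumed across genes.

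By camera of limma with a preset correlation of 0.01, which tests a list against the other genes, 4 of 22 lists passed for the shared effect. Hypoxia and glycolysis genes ranked low (adjusted p = 2.05e-05; p = 0.118 with an estimated correlation), as did interferon-stimulated genes (adjusted p = 0.0241; p = 0.204 with an estimated correlation). Core spliceosome genes, whose K562 median was -0.01, ranked high (adjusted p = 0.0152; p = 0.527 with an estimated correlation), as did respiratory chain genes (adjusted p = 0.0351; p = 0.547 with an estimated correlation). With an estimated correlation 0 of the 22 passed, at an adjusted p of 0.983 for each, and fry called 0. With 1 residual degree of freedom both tests have little power. The correlation is also poorly estimated, at 1 for the double-stranded RNA sensors and -0.2 for the interferon list. These zeros therefore do not decide about the 4 lists, whose calls rest on the preset correlation. The interferon list rests on 6 genes kept in both lines, and it did not pass after loess (adjusted p = 0.0525) or with no filter (0.628). The respiratory chain did not pass after quantile normalization (0.0537), centring (0.0695), loess (0.0525) or at the 75th percentile (0.278), nor did the spliceosome at the last of these (0.16).

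The differences of the 2 lines were set against each other to see how far they ran the same way. Across 6204 genes, which are not independent replicates, Pearson's r was 0.0329 and Spearman's rho 0.0391, and 47.1% of genes had the same sign. The median differences of the genes kept in each line had opposite signs, 0.11 on the arrays labelled HepG2 and -0.07 in K562. Such offsets alone lower the share with the same sign. ADAR alone was at least 2-fold lower in both lines, where independent lists would give 0.0598 genes, and 0 genes were 2-fold higher in both. TUBA1B was 2-fold apart in opposite directions. At 1.5-fold, CPN1, DNM1L and DMAC1 were higher in both lines (1.51 by independent lists), and ADAR, HGSNAT and BTBD2 lower in both (1.85), while 15 genes went opposite ways (5.56).

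**Figure D3:**
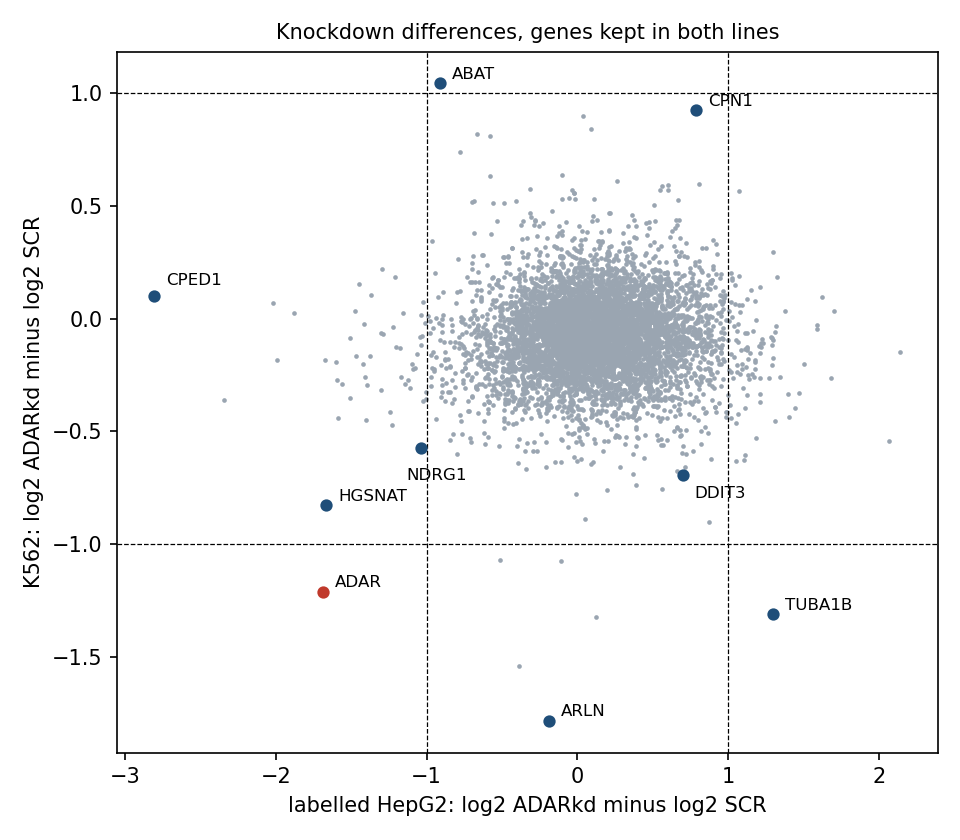
Log2 difference, ADARkd minus SCR, on the arrays labelled HepG2 (horizontal axis) against K562 (vertical axis), each point 1 of the 6204 genes kept in both lines, with dashed lines at a 2-fold difference. ADAR (red) is the only gene beyond both lines on the lower left, at -1.69 and -1.21, and TUBA1B lies at 1.30 and -1.31.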

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

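All tests of explanations in this part were chosen after the result they bear on was seen.

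On the arrays labelled HepG2 hepatocyte transcripts were low. Weak signal there cannot be judged from the 1184 genes that passed limma's test at 2-fold or more above K562. The named RMA can scale arrays to a common distribution, and the array medians were near equal. A weak array could then also give such genes, so weak signal stays open. An exchange with the K562 arrays is argued against by 13 of 17 erythroid markers that passed as higher on the arrays labelled K562. RNA from cells other than HepG2 in these libraries and loss of the hepatocyte programme in HepG2 cells cannot be told apart: the 2 of 28 hepatocyte markers at or above the median of all genes are the pattern itself and decide neither.

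The 2 arrays labelled HepG2 differed far more than the K562 pair, with 287 against 11 genes at least 2-fold apart. A trend with intensity is argued against as the whole cause, since 274 genes were 2-fold apart after loess. For 137 of these 274 genes, those also kept in K562, a response to lower ADAR shared by both lines is argued against. Their median K562 difference in the same direction after loess was -0.00038, inside the range of random genes (-0.04 to 0.04). The rest of the 274, such as CXCL8, IL6, COL3A1 and LOX, were not kept in K562, so a shared response of them was not tested. ADAR was also lowered less in K562, to 43.2% of its SCR intensity against 31.0% on the arrays labelled HepG2. Fibroblasts in the SCR culture, a response to lower ADAR particular to these cells and a difference between the transfected populations unrelated to ADAR cannot be told apart with 1 array per arm. Of 14 stromal markers 5 were at least 1.5-fold lower in ADARkd, as fibroblasts in the SCR culture would give, 2, LUM and DCN, were higher, and 6 lay under the filter level on the SCR array.

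In K562 the difference depended on intensity, with a median of 0.16 in the lowest of 10 bins of genes by level and -0.07 in the highest. The arrays labelled HepG2 had a trend the other way, from -0.03 in the lowest bin to 0.16 in the highest, so a trend is not particular to K562. Another background level on the K562 ADARkd array is a candidate explanation: 225 olfactory receptor genes, mostly silent outside the nose, had a median K562 difference of 0.20, against 0.15 for genes at their level. A rise of weakly expressed genes through ADAR loss cannot be told apart from it: the lowest bin on the arrays labelled HepG2, at -0.0285, does not bear on a rise in K562 alone.

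Several genes went opposite ways in the 2 lines, and none of these differences was tested, because the design leaves no replicate for it. ABAT differed by -0.91 on the arrays labelled HepG2 and by 1.04 in K562, MYCN by -0.66 and 0.82, and ZSCAN20 by -0.78 and 0.74. TUBA1B, which has near-identical paralogs, differed by 1.30 and -1.31, and DNAJC8 by 0.87 and -0.90. DDIT3, a stress-induced transcription factor singled out here after its values were seen, differed by 0.70 and -0.69. The median of the ATF4 and unfolded protein response list was 0.35 on the arrays labelled HepG2 and -0.23 in K562. Among transcript clusters outside every comparison, 13 with several gene symbols and 6 with none were at least 2-fold higher in the ADARkd array labelled HepG2 than in its SCR array, and 17 and 8 were at least 2-fold lower.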

How the results depend on the processing

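The alternatives added after the data were seen were the leave-one-out fits, the 75th percentile filter for lists and the offset for ADAR. ADAR was lower in both lines under every alternative. With log2(value + 16) the genes 2-fold apart were 186 on the arrays labelled HepG2 and 7 in K562; an offset shrinks differences of dim genes. With no filter K562 had 30, the correlation between the lines was -0.0828, and the interferon-stimulated list's median in K562 was 0.10, above that of random lists rather than below; the cause was not tested. The filter at the 75th percentile, which tests fewer genes, gave 116 on the arrays labelled HepG2, 1 in K562, 1159 for K562 against HepG2, 1 list in the shared effect and 5 extreme lists for HepG2 against 8: ATF4, spliceosome and cell cycle genes lay inside the central 95%, stromal markers were too few, and ribosomal proteins lay outside. At 1.5-fold the counts were 1314 and 75, with 6 genes the same way in both lines. For the shared effect, 2 lists passed after loess, 0 with an estimated correlation and 0 with fry, the last 2 having little power with 1 residual degree of freedom. Centring on the column median gave 7 genes by limma, ADAR at -1.44 with an adjusted p of 0.000658, against a range from 0.000658 to 1.0 over all alternatives. That setting's total degrees of freedom were 96.6 against 8.6 without it. In simulated data with the prior overestimated, false calls averaged 14.4% at a change of 1. With no gene altered there were on average 8.07 false calls in such runs, so any of the 7 calls under centring may be false. CPED1, among the 7, differed by -2.81 on the arrays labelled HepG2 and by 0.10 in K562. Leaving out each array in turn gave 1489 to 2162 genes for K562 against HepG2, and the shared ADAR value lay between -1.69 and -1.21 without either line. Of the other values that answer a comparison, 84 stayed the same (counts within 1.5 times, ADAR in a line within 0.58, the correlation between the lines within 0.1, shared ADAR not passing), and 16 moved and 1 passed newly, all given here. Some of the 84 could not have moved. The shared ADAR value without 1 line is the other line's difference, and neither centring nor the 1.5-fold threshold can alter the correlation. Of the values of named genes (within 0.58) and of lists called in a line (median within 0.1) or for the shared effect (same side of the threshold), 341 stayed the same, 17 moved and 7 no longer passed. In that group 1 passed newly (NF-kB and cytokine targets in the shared effect with no filter, adjusted p = 0.000678) and 3 reversed: the interferon median above and the K562 spliceosome median, at 0.0673 after quantile normalization and 0.0631 after loess. The medians of all lists within a line, called or not, were less stable. On the arrays labelled HepG2, 14 of 164 medians under alternatives turned sign, 35 more moved by over 1.5 times and 9 crossed the bounds of the central 95%; in K562 these were 15, 50 and 7 of 164. Signal over background was not analysed here.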

Other observations

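The gene families in this part were chosen after the data were seen, and they have no test, since each line has 1 array per arm.

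Many subunits of the proteasome, the complex that degrades ubiquitin-tagged proteins, were higher in the ADARkd array labelled HepG2. Of 27 kept subunits, 16 were at least 1.5-fold higher and 0 lower, and 6 were 2-fold higher. PSMD1 differed by 1.23, PSMB1 by 1.22 and PSMA3 by 1.12. The median was 0.65, and it was 0.59 after quantile normalization and 0.52 after loess. In K562 the median of 26 subunits was -0.01 and turned positive after quantile normalization (0.04) and loess (0.05).

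Of 13 kept collagens on the same array, 6 were at least 1.5-fold lower and 1, COL5A2 (1.22), higher, with a median of -0.46 that stayed negative under each scaling. COL1A1 and COL3A1 are also among the fibroblast and stromal markers, whose median was -0.83, so this is not a separate observation. Of 3 kept LOX enzymes, which crosslink collagen, LOX (-2.18) and LOXL2 (-1.11) were lower, with a median of -1.11 that was -1.25 after quantile normalization. Genes with symbols of the interleukin and CXC chemokine kind ran the other way. Of 50 measured, 10 were kept, and 9 of these were at least 1.5-fold higher. The median of the 10 was 1.28 (1.17 after loess), and IL18 differed by 1.69. CXCL2 (1.74) and IL1B (0.78) are also among the NF-kB and cytokine targets, whose median was 0.78, so this family is not a separate observation. The 9 include a receptor, IL4R (0.64). They also include CXCL8 and IL6, whose SCR levels of 4.36 and 3.16 lay under the filter level of 5.31. Both kept EGF receptor ligands, EPGN (2.75) and EREG (1.13), were higher under each scaling. Integrins went both ways: of 9 kept, ITGA6 (1.64) and ITGB8 (1.61) were at least 1.5-fold higher and ITGB5 (-0.61) lower, and the median of 0.01 turned negative after quantile normalization (-0.08) and loess (-0.10). In K562 the 5 kept integrins had a median of -0.39 (-0.29 after quantile normalization).

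In all, 12 families were looked at. The rest on the arrays labelled HepG2 were keratins (median 0.32), the T-complex chaperonin (0.28, and 0.16 after loess), tubulins (0.23, and 0.08 after loess), lysosomal cathepsins (-0.22, and -0.37 after loess) and 111 zinc finger genes with the ZNF stem (0.11, and 0.03 after loess). The median of 120 solute carriers was 0.07 and turned negative after quantile normalization (-0.03) and loess (-0.04).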
